A study of Drosophila melanogaster with 4 samples.

How the data were processed

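RNA was taken from whole, dechorionated Drosophila melanogaster embryos collected over 0 to 24 h from flies kept at 25 °C, per the labels. The mutant embryos carried a null allele of dsap18, the fly gene for SAP18 (current symbol Bin1), over a deficiency that removes the gene. The control embryos had the same genotype plus a transgene that expresses HA-tagged dSAP18. Per the labels' protocols, 1.5 µg of total RNA per sample was amplified, labelled through amino-allyl groups with Cy3 or Cy5 and hybridised to two-colour arrays. There were 4 arrays, which make up 2 biological replicates from different extractions. Each replicate was hybridised on 2 arrays with the same amplified RNA and the dyes swapped, so these 2 arrays are technical repeats and n is 2. The label of 1 control channel of replicate 1 places the rescue transgene on chromosome 2, and the labels of the other 3 arrays place it on X, including the dye swap of the same RNA.

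The deposited table holds the authors' log ratio of the channels, taken here as log2, for each spot and array. The submitters' processing notes name limma, with no version. The background correction, the normalization and the rule that left spots empty are not given in the sources used here. The base of the logarithm is itself not stated, and limma's log ratios are to base 2. The values ran in the same direction on arrays of opposite dyes (all 4 columns correlated positively across genes), so the authors' values were taken as already turned one way, and no sign was changed here, although the design fixed beforehand had foreseen turning the swapped arrays. In ratios not turned, a gene-specific dye bias that is identical in both replicates would not make swapped arrays of a replicate correlate more closely than arrays with the same dyes, as they did. A dye bias that differs between replicates could give the same correlations, and no value used here tells that case from turned ratios. Which of mutant over control and control over mutant the deposited ratio is remains unstated. Mutant over control is the likely direction, because the series text treats the mutant as the sample and the other channel as the reference. The medians of the 4 arrays over all their values were 0.00, 0.01, 0.01 and 0.01, so the ratios were centred near 0.

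The table has 16416 spots. In the platform annotation used, 13163 spots had 1 gene symbol, 101 had several and 3152 had none. Symbols were updated through the Release 6 RefSeq gene table, with 12532 named spots matched by gene ID and 120 by accession, while 511 kept the annotation's symbol. No genome build is given for the arrays, so that table served only for names, neighbours and chromosome arms, and no coordinates are printed. Spots with values numbered 7976 and 7642 on the arrays of replicate 1 and 6893 and 6537 on those of replicate 2, which is 48.6%, 46.6%, 42.0% and 39.8% of all spots. Spot intensities were not used here, so signal over background is unknown, and the number of arrays limits the precision. On all 4 arrays 5398 spots had a value. Of these, 4501 had exactly 1 symbol and were averaged into 4312 genes. The 871 unnamed spots, which can include control features, and the 26 spots of several genes were left out. Of 108 genes with more than 1 spot, 36 had spots of different sign and 2 had spots that differed by over 1 in log2 ratio.

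For each gene the 2 swapped arrays of a replicate were averaged, so that a dye effect cancels if the ratios were turned, and the 2 replicate means were tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg over 4312 genes). A gene passed at an adjusted p under 0.05. All adjusted p-values given for genes are limma's. With 1 residual degree of freedom per gene, the test borrows nearly all of its variance from the other genes (48.9 prior degrees of freedom, prior SD 0.229). A count of genes beyond 2-fold with the same sign on all 4 arrays was made beside it, with no test. Errors are given as the SD of the 2 replicate means.

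Before the data were examined, 28 gene lists were fixed. They were SAP18 partners, heat shock proteins and chaperones, antimicrobial peptides and humoral immunity, glutathione S-transferases, cytochrome P450s, antioxidant enzymes and metallothioneins, stress kinase, TOR/FOXO and JAK-STAT signalling, cell death, segmentation genes, Hox genes, dosage compensation and sex determination, maternal and germ plasm transcripts, cellularisation transcripts, egg shell and yolk, cuticle proteins, chitin and epidermal barrier, muscle, neurons, glia, hemocytes, fat body and basement membrane, midgut digestive enzymes, trachea and salivary gland, ecdysone biosynthesis and response, cell cycle, ribosomal proteins, proteasome, histones, and transgene and background markers. Of the symbols in them, 4 were not matched to the gene table. Lists with at least 3 measured members were compared with all other genes by limma's camera (preset inter-gene correlation 0.01, two-sided, Benjamini-Hochberg over 24 lists), and again with an estimated correlation and with fry. Lists built from symbol prefixes take in HisRS, a tRNA ligase, among the histones, and Cyp1 and Cyp40, both cyclophilins, among the cytochrome P450s. Medians of genes within 100 kb of Bin1 and of each chromosome arm were set among the medians of 10000 random lists of the same size.

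The rule for named genes was also fixed beforehand: Bin1, the 12 lowest and 12 highest mean log2 ratios among genes that passed with the same sign on all 4 arrays, and up to 4 members of each list with the largest mean ratios of the same sign on all 4 arrays. Names outside the rule were chosen after their values were seen. The gene test was tested on simulated data of 4312 genes for this comparison, with 200 genes changed in each of 20 sets and normal noise of the same SD for every gene. It recovered 47.2% of changes of 0.5, 99.9% of changes of 1 and 100% of changes of 2 in log2 ratio, and 4.55% of its calls were false. The simulation holds no variance that differs between genes and no scale that differs between replicates, both of which can make the real calls less certain. With no gene changed, 0.0833% of lists were called, and the cuticle list moved by 0.5 was called in 100% of 50 simulations, all with independent genes.

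The alternatives fixed beforehand were all 4 arrays with the replicate as a random block, as independent arrays or with a dye term, each dye orientation alone, median centring, scaling and quantile normalization of the arrays, a robust variance prior, genes with at least 1 array per replicate, each spot on its own, a filter on genes noisy between swaps, a test against a log2 ratio of 0.58, and each replicate left out. The unnamed spots as features, a test with no variance moderation and a run with the values turned by the dyes were added after the data were seen. A Fisher test of late against early lists, a permutation test of the immunity list against late-tissue genes and a comparison of Drs with Drsl5 were also made and are not reported, because their groups or genes had been chosen after the values were seen. The comparison of the cellularisation list with lists of other ages took the place of the first of them and was itself chosen after the values were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.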

Results

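Transcript levels were compared between whole Drosophila melanogaster embryos with a null dsap18 allele over a deficiency and embryos that also carry a dsap18-HA transgene. How much dSAP18 either kind of embryo held was not measured here. SAP18 is a small nuclear protein found with the Sin3 histone deacetylase complex and with the splicing-associated ASAP complex. The comparison asks which transcripts depend on dSAP18 during embryogenesis. It rests on 2 biological replicates of embryos aged 0 to 24 h, each measured on 2 arrays with the dyes swapped, and covers 4312 genes with values on all 4 arrays. Each array had values for between 6537 and 7976 of 16416 spots.

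The targeted gene could not be used to check the labels, because no spot was named for Bin1 (dSAP18) in the annotation used and its level was not analysed here. The direction of the deposited ratio is not stated and nothing in the table settles it. In the likely direction, mutant over control, a negative log2 ratio means a lower level in the mutant and a positive one a higher level. If the ratio is control over mutant, every sign in the text turns, while the sizes, counts and groupings stay as they are. The ratios ran the same way on arrays of opposite dyes and were taken as already turned to one direction. That was not stated either. In ratios not turned, the means would hold dye effects, and the swapped arrays of a replicate would not correlate more closely than arrays with the same dyes, as they did, unless the dye effects differed between replicates. The log base was taken as log2.

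Immune peptide genes were among those with the most negative ratios, and a linker histone gene and a germline gene among those with the most positive. Drs (NCBI gene 38419), which encodes the antifungal peptide Drosomycin, had a mean log2 ratio of -3.06 ± 1.60 (SD, n = 2), an 8.34-fold difference (limma adjusted p = 1.15e-14). BomS2, a Bomanin immune peptide gene, followed at -2.39 ± 0.89, and another Bomanin, BomS5, was at -1.31 ± 0.66. The other genes among the 12 lowest were CG2233 (-1.96), CG18180 (-1.58), CG16713 (-1.56), CG9759 (-1.52), CG9757 (-1.33), CG13738 (-1.27), the ribosomal protein gene RpL27 (-1.17), the lipoprotein gene apolpp (-1.13) and neo (-1.13), which encodes a zona pellucida domain protein of the epidermis. At the other end stood CG5568 (NCBI gene 38658) at 1.61 ± 0.52 (3.06-fold, limma adjusted p = 7.74e-10), the histone H1 gene His1:CG31617 at 1.31 ± 0.87 and CG11263 at 1.26 ± 0.93. They were followed by mael (1.14), a gene of the piRNA pathway, Drep1 (1.12), the ribosomal protein gene RpS21 (1.10), CG32625 (1.05), the Drosomycin-like gene Drsl5 (1.03), the spindle gene mei-38 (1.01), the securin gene pim (0.99), Pus10 (0.98) and Idgf4 (0.98).

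In all, 999 of 4312 genes (23.2%) passed the limma test, 509 with a negative and 490 with a positive ratio, and 983 of them had the same sign on all 4 arrays. For 232 of them the difference between the replicates exceeded the mean ratio. The smallest ratio that passed was 0.421 in size. Beyond 2-fold with the same sign on all 4 arrays there were 27 genes with a negative and 9 with a positive ratio. The gene calls rest on a variance pooled over genes: tested gene by gene without moderation, no gene passed and 354 had an unadjusted p under 0.05, against 1555 with limma. The count beyond 2-fold depends on the replicate, since replicate 1 alone gave 10 negative and 2 positive genes and replicate 2 alone 136 and 59.

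**Figure D1:**
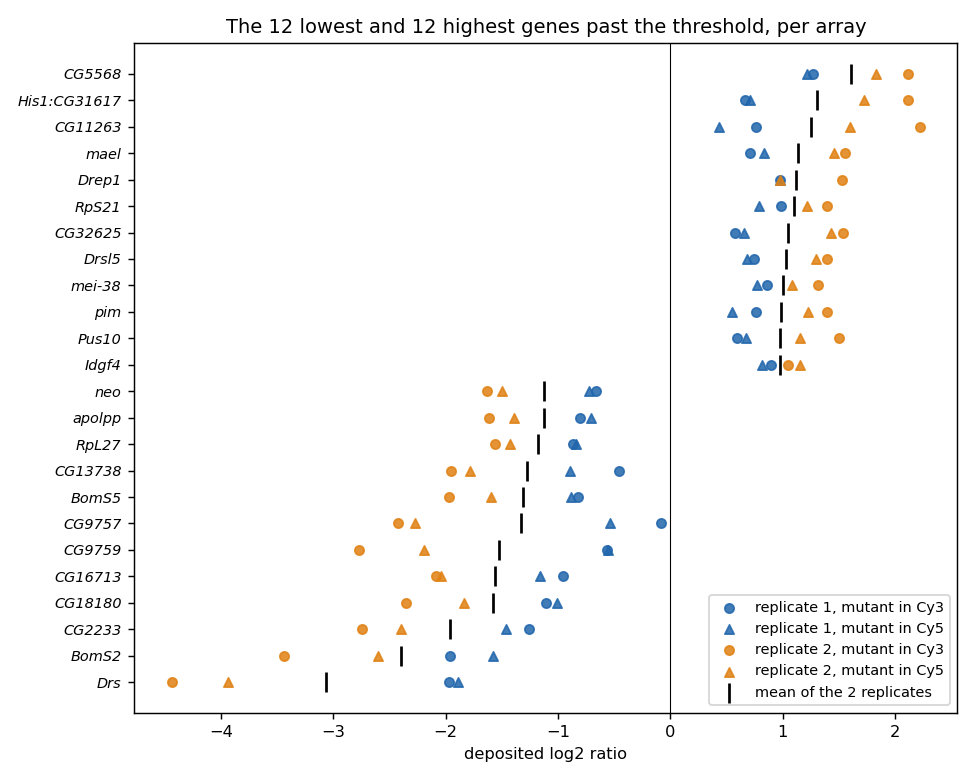
Deposited log2 ratios (horizontal axis) of the 12 lowest and 12 highest genes past the limma test, with a symbol for each of the 4 arrays and a bar for the mean of the 2 replicates. Drs lies at -1.97 and -1.89 on the arrays of replicate 1 and at -4.44 and -3.94 on those of replicate 2, and arrays of a replicate lie closer to each other than to the other replicate for most genes.

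Swapped arrays of a replicate correlated across the 4312 genes with Pearson r = 0.84 in replicate 1 and 0.92 in replicate 2. Between replicates r was 0.74 for both pairs of arrays with the same dyes and 0.67 and 0.69 for pairs with swapped dyes. The replicate means correlated with r = 0.756 and Spearman rho = 0.758. These values are across genes, which are not independent replicates. The same sign on all 4 arrays was found for 2723 genes (63.2%). Ratios were wider in replicate 2, with an SD over genes of 0.50 against 0.28 in replicate 1, which is 1.80 times as wide.

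**Figure D2:**
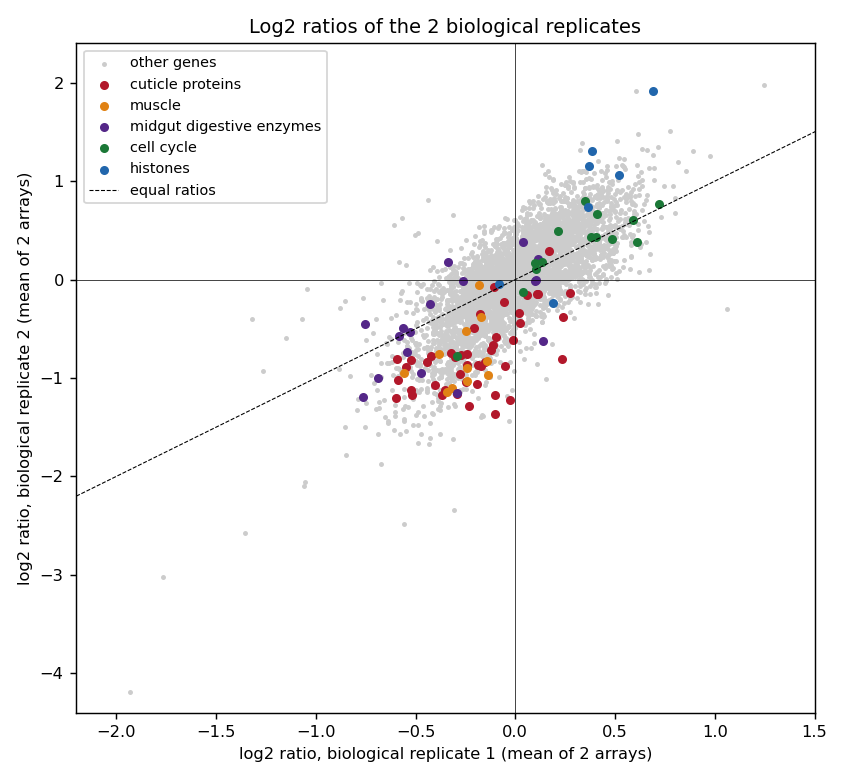
Mean log2 ratio of each of 4312 genes in replicate 1 (horizontal axis) and replicate 2 (vertical axis, wider scale), with members of 5 gene lists coloured and a dashed line at equal ratios. Cuticle and muscle genes lie mostly below the line, with list medians of -0.81 and -0.89 in replicate 2 against -0.19 and -0.24 in replicate 1, while cell cycle genes lie near it.

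Of 24 gene lists with at least 3 measured members, 13 differed from the other genes by camera with a preset correlation, 8 to the negative and 5 to the positive side. With the correlation between genes estimated, these calls were lost: 0 lists passed camera, with 0 at an unadjusted p under 0.05 and a smallest adjusted p = 0.734. By fry, which tests whether a list moves one way and does not compare it with other genes, 0 lists passed, 1 had an unadjusted p under 0.05 and the smallest adjusted p was 0.49. Both rest on 1 residual degree of freedom and had little room to call any list, so the lost calls do not show which are false. The midgut list had an estimated correlation of -0.06, below the preset 0.01, yet its unadjusted camera p rose from 6.09e-05 to 0.145. The preset calls in turn rest on that assumed 0.01. Each camera p given below is the preset one, and values with an estimated correlation carry this limit.

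Lists of the larval cuticle and of several differentiated tissues had negative medians. Among 46 cuticle protein genes the median log2 ratio was -0.53 (-0.19 in replicate 1 and -0.81 in replicate 2), 29 passed the gene test with a negative ratio and none with a positive one, and 17 did not pass (31 negative when adjusted over the list alone). The Tweedle genes TwdlF (-0.90 ± 0.43), TwdlW (-0.84) and TwdlG (-0.82) and the cuticle gene Ccp84Ab (-0.81) were the lowest (camera adjusted p = 6.40e-12, or adjusted p = 0.734 with an estimated correlation). Of 8 genes of chitin and the epidermal barrier 6 passed, all negative, with a median of -0.53 (-0.33 in replicate 1 and -0.75 in replicate 2; 6 adjusted over the list alone). They included the chitin-binding protein gene Gasp (-0.74 ± 0.22), mmy (-0.64), needed to make the chitin precursor, and the chitin deacetylase gene serp (-0.63). The camera adjusted p of this list was 6.11e-04, and the adjusted p with an estimated correlation was 0.734. The pigmentation gene y, also listed as a background marker, was at -0.50 ± 0.37 (limma adjusted p = 0.023), and it was the sole measured member of the background marker list.

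Muscle genes had a median of -0.57 (-0.24 in replicate 1 and -0.89 in replicate 2) over 11 members, of which 8 passed, all negative (9 adjusted over the list alone). Tropomyosin Tm2 was at -0.75 ± 0.28, troponin C TpnC73F at -0.74 ± 0.57 and myosin light chain Mlc2 at -0.71 ± 0.55 (camera adjusted p = 3.87e-05, or adjusted p = 0.734 with an estimated correlation). The list of hemocytes, fat body and basement membrane had a median of -0.69 (-0.39 in replicate 1 and -1.11 in replicate 2), with 8 of 9 members past the test, all negative (8 adjusted over the list alone). The prophenoloxidase PPO2, an enzyme of crystal cells, was at -0.97 ± 0.53, and the basement membrane genes LanB2 (-0.94), LanA (-0.85) and Col4a1 (-0.77 ± 0.86) were also low (camera adjusted p = 1.82e-06, or adjusted p = 0.734 with an estimated correlation). Of 17 digestive enzyme genes of the midgut 9 passed, all negative, with a median of -0.53 (-0.34 over the larger set of genes with at least 1 array per replicate; 9 adjusted over the list alone). The serine proteases Jon25Bii (-0.98 ± 0.30) and Jon99Ci (-0.84) and the maltase Mal-A3 (-0.73) were examples (camera adjusted p = 3.65e-04, or adjusted p = 0.734 with an estimated correlation). Most that passed were Jon genes, and of the other members only Mal-A3 and epsilonTry (-0.60) passed. The other members that did not pass lay between -0.24 (Mal-A4) and 0.21 (Ser6). Genes outside the naming rule here were named after their values were seen. Of 4 glial genes 3 passed, all negative, with a median of -0.55 (-0.37 in replicate 1 and -0.72 in replicate 2; 3 adjusted over the list alone). These were Gs2 (-0.78), nrv2 (-0.58) and the glial transcription factor gene repo (-0.51), with a camera adjusted p = 0.0137, or adjusted p = 0.734 with an estimated correlation. None of 5 neuronal genes passed (median -0.14, -0.03 in replicate 1 and -0.24 in replicate 2, camera adjusted p = 0.428, none adjusted over the list alone), with Gad1 at -0.42 ± 0.43. The difference between the glial and neuronal lists was not tested.

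The list of ecdysone synthesis and response had 7 measured genes, with no gene for an enzyme of ecdysone synthesis among them. Of these 7 genes 4 passed, all negative, and the median was -0.46 (-0.13 in replicate 1 and -0.80 in replicate 2; 4 adjusted over the list alone). The ecdysone-inducible genes ImpE2 (-1.0 ± 0.36) and ImpL1 (-0.78 ± 0.28) and the nuclear receptor genes Hr39 (-0.49 ± 0.51) and Hr3 (-0.46 ± 0.48) were those 4. The camera adjusted p was 0.0082, against an adjusted p = 0.734 with an estimated correlation, and the call was lost without the genes noisiest between swaps (adjusted p = 0.0562). The median shrank to -0.11 in that setting, which leaves list members out, and also over genes with at least 1 array per replicate.

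The immunity list moved both ways. Of 11 measured members 6 passed with a negative ratio, namely Drs, BomS2, the lysozyme genes LysD (-0.63 ± 0.12), LysB (-0.48) and LysE (-0.45), and the NF-kappaB gene Rel (-0.53 ± 0.38). The receptor gene Tl (0.47) and the inhibitor gene cact (0.42) of the Toll pathway passed with a positive ratio, Tl not with the same sign on all 4 arrays. LysB, LysE, Tl and cact were named after their values were seen. The counts were the same when adjusted over the list alone. The median was -0.45 (-0.26 in replicate 1 and -0.39 in replicate 2; camera adjusted p = 0.0017, or adjusted p = 0.734 with an estimated correlation). The call was lost with the 4 arrays taken as independent (adjusted p = 0.0898), with a dye term (0.112) and without the genes noisiest between swaps (0.533). That last setting leaves list members out, and the median shrank to -0.11 over those that stayed, whose own ratios the filter does not change.

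On the positive side stood histones, maternal transcripts, cell cycle genes, the proteasome and SAP18 partners. Among 7 genes of the histone list the median was 0.76 (0.37 in replicate 1 and 1.06 in replicate 2) and 5 passed, all positive (5 adjusted over the list alone). Beside His1:CG31617 these were His2B:CG17949 (0.85 ± 0.65), His4:CG31611 (0.79 ± 0.38), His2A:CG31618 (0.76 ± 0.56) and the variant His2Av (0.55), the last named after its value was seen. The HisRS and His4r spots were at -0.06 and -0.03. The core and linker histone genes exist in many near-identical copies, so their spots cannot tell copies apart. The camera adjusted p was 6.11e-04, against an adjusted p = 0.734 with an estimated correlation. The call was lost with a dye term (adjusted p = 0.0583) and without the genes noisiest between swaps (0.0881), a setting that leaves list members out. The median over the members that stayed was 0.37.

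Of 15 maternal and germ plasm transcripts 6 passed, all positive, with a median of 0.36 (6 positive and 1 negative adjusted over the list alone). The examples were plu (0.89 ± 0.39), a regulator of the early nuclear cycles, swa (0.73 ± 0.11), bcd (0.56 ± 0.01), which encodes the anterior morphogen Bicoid, and CycB (0.54 ± 0.18). The camera adjusted p was 0.0032, and the adjusted p with an estimated correlation was 0.734. Among 14 cell cycle genes the median was 0.41. With a positive ratio 6 passed, including the meiotic phosphatase gene twe (0.74 ± 0.04), fzy (0.60 ± 0.01) and PCNA (0.57 ± 0.31), and 1 passed with a negative ratio, E2f1 (-0.53), named after its value was seen. Adjusted over the list alone these counts were 9 and 1 (camera adjusted p = 0.0044, or adjusted p = 0.734 with an estimated correlation).

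Proteasome genes had a median of 0.29 over 27 members, but the list was split. All measured core subunit genes (Prosalpha and Prosbeta) had a positive mean ratio, while most Rpn and Rpt genes had a negative one. Of the Rpn and Rpt genes only Rpt4 passed with a positive ratio. This split was made after the values were seen and was not tested. With a positive ratio 10 passed, among them the core subunit genes Prosbeta3 (0.86 ± 0.74), Prosalpha4 (0.64) and Prosalpha3 (0.63) and the base ATPase gene Rpt4 (0.66), and 1 passed with a negative ratio, Rpt5 (-0.43), named after its value was seen. Adjusted over the list alone 11 were positive and 1 negative. The median was 0.05 in replicate 1 and 0.52 in replicate 2. The camera adjusted p was 0.0139, against an adjusted p = 0.84 with an estimated correlation, and the call was lost with the replicate as a random block (adjusted p = 0.0609), with independent arrays (0.205) and with a dye term (0.236).

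Of 10 genes for partners of SAP18, 3 passed, all positive: the gene for the histone-binding p55 subunit of chromatin assembly factor 1 (0.71 ± 0.09), bcd and the deacetylase HDAC1 (0.44 ± 0.14). RnpS1, a member of the ASAP complex, was at 0.39 ± 0.24 and did not pass, and 4 genes passed when adjusted over the list alone. The median was 0.33, with a camera adjusted p = 0.0323, or adjusted p = 0.734 with an estimated correlation. The call was lost in 4 further settings, among them the arrays with the mutant in Cy3 alone (adjusted p = 0.0532) and each spot on its own (0.0916). The transcript bcd counts in this list, the maternal list and the segmentation list, and CycB in the maternal and cell cycle lists.

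**Figure D3:**
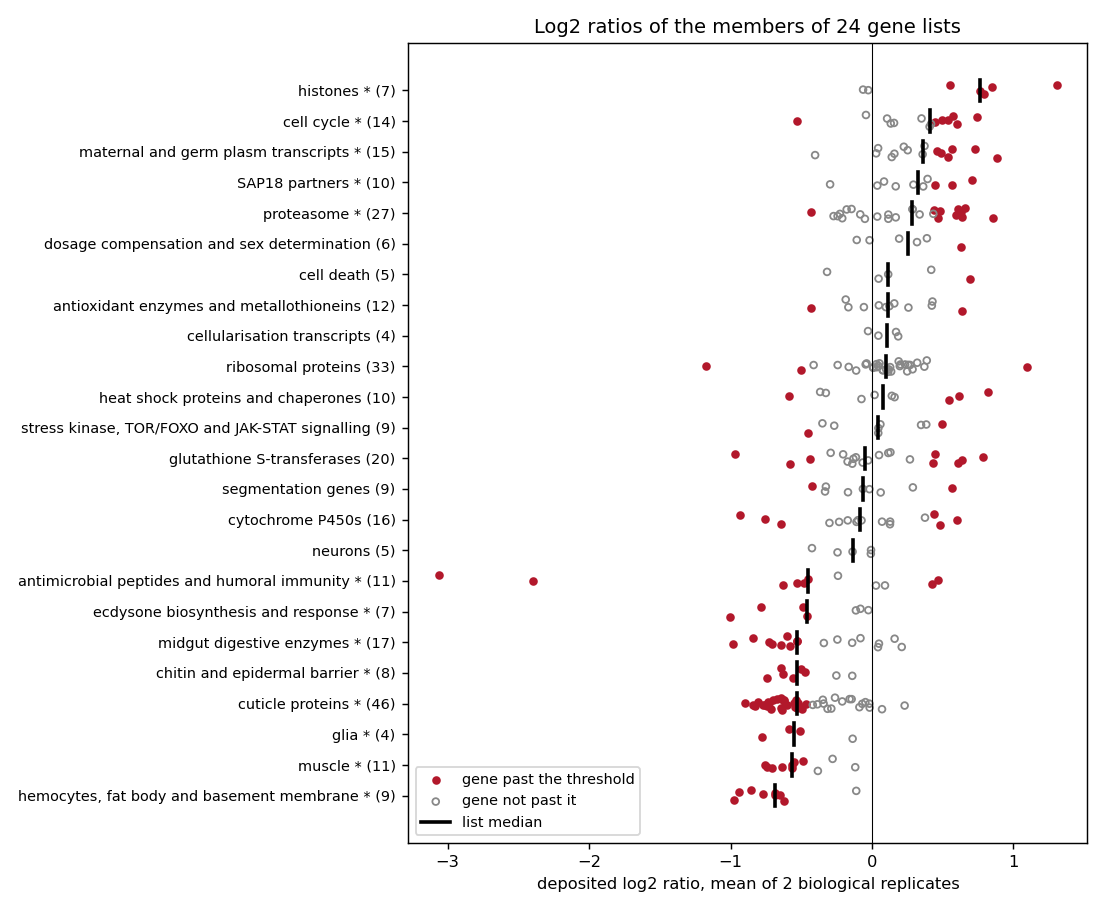
Deposited log2 ratios (horizontal axis, mean of the 2 replicates) of the members of 24 gene lists, ordered by list median, with the number of members in parentheses. Filled points are genes past the limma test, open points are genes that did not pass, black bars are list medians and asterisks mark lists past camera with the preset correlation. Medians run from -0.69 in the list of hemocytes, fat body and basement membrane to 0.76 in the histone list.

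The remaining lists did not differ from other genes by camera. Among 33 ribosomal protein genes the median was 0.10 (0.04 in replicate 1 and 0.18 in replicate 2, adjusted p = 0.428), yet RpL27 (-1.17 ± 0.45) and RpS21 (1.10 ± 0.30) were among the most extreme genes on either side, and RpLP2 also passed at -0.50 ± 0.08. These 3 passed when adjusted over the list alone as well. Of 10 heat shock and chaperone genes Hsp26 (0.82 ± 0.70), Hsp70Bc (0.61 ± 0.03) and Hsp27 (0.55 ± 0.40) passed with a positive ratio and the mitochondrial Hsc70-5 (-0.59 ± 0.22) with a negative one. The median was 0.08 (0.05 in replicate 1 and 0.08 in replicate 2, adjusted p = 0.614), and the same 3 and 1 held adjusted over the list alone. Counted spot by spot this list passed with a median of 0.60 (adjusted p = 1.98e-06), because Hsp70Bc alone has 17 spots.

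Detoxification genes moved both ways. Of 20 glutathione S-transferases 3 passed with a negative ratio, led by GstE6 (-0.97 ± 0.40), and 5 with a positive one, led by GstO1 (0.79 ± 0.46). Their median was -0.05 (-0.08 in replicate 1 and 0.06 in replicate 2), while the mean (0.02) and the camera direction were positive (adjusted p = 0.889). Of 16 genes in the cytochrome P450 list 3 passed on each side, with Cyp304a1 at -0.94 ± 0.53 and Cyp6v1 at 0.60 ± 0.11, and 1 of the positive ones was the cyclophilin Cyp40 (median -0.09, -0.08 in replicate 1 and 0.06 in replicate 2, adjusted p = 0.62). Adjusted over the list alone the counts were unchanged in both lists. Of 12 antioxidant and metallothionein genes Sod3 (0.64 ± 0.49) and Gclc (-0.43) passed, and 1 negative and 3 positive genes did so adjusted over the list alone (median 0.11, -0.01 in replicate 1 and 0.26 in replicate 2, adjusted p = 0.434).

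Among 9 genes of stress kinase, TOR/FOXO and JAK-STAT signalling lic (0.49 ± 0.08) and the JNK gene bsk (-0.45 ± 0.07) passed (median 0.05, -0.03 in replicate 1 and 0.07 in replicate 2, adjusted p = 0.834). The initiator caspase gene Dronc (0.69 ± 0.21) passed alone of 5 cell death genes (median 0.12, 0.21 in replicate 1 and 0.02 in replicate 2, adjusted p = 0.392), with Dcp-1 at 0.42 passing only when adjusted over the list alone. Of 9 segmentation genes bcd and opa (-0.43 ± 0.12) passed (median -0.06, -0.02 in replicate 1 and -0.20 in replicate 2, adjusted p = 0.732), and of 6 genes of dosage compensation and sex determination ix (0.63 ± 0.21) did (median 0.26, adjusted p = 0.192). None of 4 cellularisation transcripts passed (median 0.11, -0.21 in replicate 1 and 0.33 in replicate 2, adjusted p = 0.699), with nullo at 0.17 ± 0.06. Its other members, named after their values were seen, differed by replicate. They were halo at -0.44 in replicate 1 and 0.81 in replicate 2, Sry-alpha at -0.50 and 0.45, and slam at 0.01 and 0.08. The cause of these changes of sign was not tested. For these lists other than cell death the counts were the same when adjusted over the list alone. Hox genes, egg shell and yolk genes, and tracheal and salivary gland genes had 1 measured member each. These were Antp (-0.35, not passed, limma adjusted p = 0.12), Vm34Ca (-0.04, not passed) and uif (-0.59 ± 0.39, limma adjusted p = 0.0076). Antp did not keep its sign on all 4 arrays. Its unadjusted limma p was 0.0408, which adjusting over a list of 1 member leaves unchanged.

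Position in the genome was examined because the control carries a transgene that the mutant lacks, and both carry a deficiency. The 7 measured genes within 100 kb of Bin1 had a median log2 ratio of 0.16, at percentile 80.5 of 10000 random lists of the same size, and Mic26-27 (0.72 ± 0.52) and mtSSB (0.60 ± 0.58) passed the gene test. Among chromosome arms the 612 genes of the X chromosome had a median of 0.06 (percentile 99.8), the 880 of 3L a median of -0.02 (percentile 0.85) and the 901 of 2R a median of -0.02 (percentile 4.23). The 1064 genes of 3R, the arm of Bin1, had a median of 0.01 (percentile 43.5), the 781 of 2L of 0.02 (percentile 74.6) and the 32 of chromosome 4 of -0.08 (percentile 12.2). These percentiles describe the arrays and are not tests across replicates.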

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

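Each named gene and 3 measures of the arrays, 108 items in all, were examined for an array that stood apart from the other 3, which chance gives in about 1 of 20 items of 4 independent arrays. Swapped arrays share their RNA, so that rate does not hold here. The criterion was met by 2 items. For Drep1, whose product is related to an inhibitor of a caspase-activated DNase, the array of replicate 2 with the mutant in Cy3 read 1.53 and the other 3 read 0.98 (0.991 of the range lay in the gap). For lic, a kinase of the p38 pathway, the array of replicate 1 with the mutant in Cy3 read 0.33 and the other 3 between 0.54 and 0.56 (0.921 of the range). In both cases the dye swap of the same RNA was among the other 3 arrays, and all 4 arrays had a positive ratio.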

How the results depend on the processing

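The test without variance moderation, the runs with unnamed spots and the run with swapped arrays turned by their dyes were chosen after the data were seen. Turned in this way, as if the deposited ratios had not been turned, 149 genes passed (73 negative, 76 positive), 0 lay beyond 2-fold with the same sign on all 4 arrays, and camera called 1 list, cuticle proteins, at a median of 0.05. Of the 91 named genes past the threshold 4 passed there. These counts follow from the positive correlation of all 4 arrays and do not test whether the ratios had been turned. In the other settings no named gene past the threshold and no called list turned its sign. Under 9 other settings of the gene test the total stayed within 1.5 times the 999 genes. It moved with all arrays as independent, to 2068 (986 negative, 1082 positive), with a dye term to 1571 (821 positive), with scaled arrays to 1554 (818 positive) and with quantile normalization to 1585 (830 positive). Taking swaps as independent ignores that they share RNA. The fit with a dye term also took them as independent, so its 1571 genes compare with the 2068 and not with the 999. Against a log2 ratio of 0.58, 8 genes passed (7 negative, 1 positive). Without variance moderation 0 passed (0 negative, 0 positive; 354 at an unadjusted p under 0.05, smallest adjusted p 0.305), since 1 residual degree of freedom is then left. Of 105 named genes, 83 no longer passed against 0.58 and 91 without moderation. The random block kept 914 of the 999 genes and the run with unnamed spots 785.

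The number beyond 2-fold ran from 10 to 136 negative and 2 to 59 positive genes with a replicate left out, which leaves no test. It was 14 positive with the mutant in Cy3 alone, 14 negative with scaled arrays, 12 negative without the noisiest genes, of which fewer were tested, 88 negative with unnamed spots, and 271 negative and 193 positive at 1.5-fold. Camera called 9 to 13 lists in the other settings with the preset correlation, and 0 with an estimated correlation and 0 by fry (0 and 1 at an unadjusted p under 0.05). Where not given, the cause was not tested. No alternative gave a value for Bin1. Spot intensity, and so signal over background, was not used here. No paired analysis was possible because there is 1 group of ratios.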

Other observations

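All genes and spots in the first 2 paragraphs, and the tests of explanations in the later ones, were chosen after the values were seen, while limma, camera and fry had been fixed beforehand. The following are single genes outside the fixed lists, picked by their ratios. The integrin ligand gene Tig was at -1.06 ± 0.37, the septate junction gene Nrx-IV at -1.05 ± 0.87, Tb, a cuticle protein gene that shapes the larval body, at -1.04 ± 0.57, and fon, a clotting factor gene, at -1.07 ± 0.83, all past the limma test with the same sign on all 4 arrays. The Osiris family, whose genes are expressed in cuticle-forming epithelia, had 6 measured members, of which 6 passed with a negative ratio, from -1.04 for Osi7 to -0.61 for Osi9. Its median was -0.87 as deposited and stayed negative under centring, scaling and quantile normalization. On the positive side the co-repressor gene gro was at 0.77 ± 0.45, and vret, which like mael belongs to the piRNA pathway, at 0.79 ± 0.26, while aub of the same pathway was at 0.36 and did not pass.

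Spots with no gene name were not all centred on 0. At 4 places that recur in the print pattern, 65 unnamed spots had a median log2 ratio of -1.39 (-0.84 in replicate 1 and -1.95 in replicate 2), and 56 of them lay below -1. The other 806 unnamed spots had a median of 0.00, with 5 below -1. What the 65 spots hold is not known here.

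By camera with a preset correlation, cuticle, muscle, basement membrane, gut and glial lists were negative and maternal, cell cycle and histone lists positive, while 0 lists passed with an estimated correlation (smallest adjusted p = 0.734, 0 at an unadjusted p under 0.05) and 0 by fry (1 at an unadjusted p under 0.05). The last 2 rest on 1 residual degree of freedom and had little room to call a list. In ratios not turned, a dye bias identical in both replicates would let swapped pairs of arrays correlate no more than pairs with the same dyes, but the product of their correlations was 1.41 times as large (bootstrap 95% interval over genes, which are not independent, 1.36 to 1.46), which argues against it. A dye bias that differs between replicates stays open, because there was no value for Bin1 to show the direction of the ratios. On all 4 arrays 13 of the 13 called lists kept the sign of their median, which does not decide it. Such a bias would also give this in ratios not turned, and the lists were called on these same arrays. A different mix of embryo ages in the RNA of mutant and control is a candidate explanation that also stays open. Of the lists tagged by embryo age beforehand, the maternal list (early, 0.36) and the cuticle list (late, -0.53) lay on opposite sides, as such a mix would give. The cellularisation list, tagged beforehand as of blastoderm age, had a median of 0.11 (-0.21 in replicate 1 and 0.33 in replicate 2). The rest of the grouping by age was made after the signs were seen. Segmentation (-0.06) and neuronal genes (-0.14, or -0.03 and -0.24 by replicate) were not called. The called lists of the proteasome (0.29), SAP18 partners (0.33), immunity (-0.45) and ecdysone (-0.46) had no age tag and were not placed in the grouping, so they do not decide it. The SAP18 partners share bcd with the maternal list. Uneven collection over 0 to 24 h would change the mix, as would slower or arrested development of the mutant if the ratio is mutant over control (faster development if it is turned), and without counts or stages of the embryos these were not separated.

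Drs (-3.06), BomS2 (-2.39) and BomS5 (-1.31) were among the 12 lowest genes, while the related Drsl5 was at 1.03 and BomS6 was at 0.38 without passing. These genes were picked by their ratios, so the values do not test an explanation. Signal shared between paralogs, a different mix of ages, a difference in infection or immune state between the embryo collections, and an effect of dSAP18 on these genes all stay untested.

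List medians differed in size between the replicates, and the ratio of the medians varied between lists. If replicate 2 were replicate 1 times a single factor, all 13 called lists would share the ratio of their medians, but with bootstrap intervals at 95% over all 13 lists (Bonferroni) the lower end for cuticle genes (2.76) lay above the upper end for cell cycle genes (2.31). Of the other 11 lists 10 had intervals that overlapped both of these, several of them very wide, and the midgut interval overlapped only that of cell cycle genes. The bootstrap takes genes as independent, while cuticle genes had an estimated correlation of 0.83 (from 1 residual degree of freedom), so the intervals can be too narrow. A single factor is therefore not excluded. Ages of mutant and control that lay further apart in replicate 2 may contribute, but the ratios do not settle it. The cuticle ratio of 4.28 (95% interval for that list alone 3.14 to 7.39) lies above the 1.80 of the SDs over all genes. So do the ratios of muscle (3.69, 2.13 to 5.31) and of hemocytes, fat body and basement membrane (2.85, 2.15 to 5.24). Chitin (2.25), glia (1.95) and histones (2.87) also lie above 1.80, but their intervals span it. The same holds for ecdysone genes (6.37) and the proteasome (10.8, interval -12.1 to 12.7), which are lists outside the age grouping. Below 1.80, with intervals that span it, lie the ratios of midgut (1.16, interval -0.369 to 2.00), maternal (1.44, 0.54 to 4.97) and cell cycle genes (1.15, 0.89 to 1.99). Outside the age grouping, those of SAP18 partners (1.46) and immunity (1.50) do so as well. A ratio of medians and a ratio of SDs, which hold the noise of single genes, are also unlike measures.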
